A study of Mus musculus with 6 samples.

How the data were processed

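The series compared auditory nerve of young adult CBA/CaJ mice (1 to 3 months old) with that of aged mice (1.5 years old), with 3 samples per group. CBA/CaJ is an inbred strain used in hearing research because its hearing holds up well into adult life. Each sample was prepared from 2 cochleae, per the series' design text. Total RNA of the dissected cochlear tissue was purified with silica columns, and 100 ng of it was turned into biotin-labelled complementary RNA for an Affymetrix 3' expression array, per the labels' protocols. Such an array reads each transcript near its 3' end with 1 or more groups of short probes, called probe sets. Each array held 1 sample, in 1 colour.

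The deposited values are log2 expression values from RMA, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays alike by quantile normalization, and summarises the probes of a probe set on the log2 scale. The RMA version and any filter were not given in the sources used here. The values bore out that scale: they ran from 3.42 to 14.95, and the medians of the 6 arrays lay between 7.53 and 7.55. Quantile normalization removes any difference between samples in the overall amount of RNA, so every change given is relative to the other genes on the same array. Probe sets at the low end of the scale carry mostly background, which compresses their changes. Control probe sets for a bacterial transcript absent from mouse averaged 4.31 ± 0.030 (SD, n = 3) in the young and 4.31 ± 0.043 (SD, n = 3) in the aged samples. No detection calls, scan dates or batches were used here. The number of arrays limits the precision.

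The table held 45101 probe sets. Of these, 64 were array controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here. Entrez identifiers of 34741 of the probe sets with 1 symbol were found in the RefSeq gene table, 204 were not, and 0 symbols changed. Probe sets with several symbols or none named no gene. For each gene, the probe set with the highest mean over all 6 arrays stood for the gene, which left 18193 genes, 9010 of them with more than 1 probe set. Where another probe set of a named gene gave under 50% or over 2 times its change, or the opposite sign, the value farthest off is given with it.

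Aged was compared with young using limma 3.58.1 in R 4.3.3. A linear model was fitted per gene (lmFit) and the variances were moderated across genes (eBayes, default settings, 2.78 prior degrees of freedom). Benjamini-Hochberg adjusted p below 0.05 over all genes was the threshold, and every adjusted p of a single gene comes from this limma test. The fold is 2 to the power of the log2 difference of the group means. Error is given as SD over 3 samples for levels and as limma's standard error (SE) for changes.

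Gene lists for the cell types, tissues and pathways that the dissected nerve could hold were fixed before the data were examined, 39 in all. The 38 with at least 5 measured members were tested with camera, limma's test of whether the genes of a list rank higher or lower than all other genes, at a preset correlation between genes of 0.01. Adjustment was over the 38 lists. The correlation between genes was also estimated from the residuals, which with 3 samples per group is imprecise, and fry tested whether the genes of a list moved, on balance, one way. Counts of members past the threshold are given over all genes tested and, for most lists with any such member, adjusted over the list alone.

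The genes to be named were also fixed before the data were examined by a rule with 3 parts. The first takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out clone-like symbols. The second takes from each list up to 4 members past the threshold by size of change and, where fewer than 2 passed, the members with the smallest p up to 2, given as values. The third is a fixed set of glial, neuronal, immune and senescence genes, of which 3 are not reported here. Genes named outside the rule are said to be so. The rule gave 100 genes, of which the most informative are named.

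RNA quality was read from the control probe sets for the 3' and 5' ends of Gapdh and beta-actin, with exact two-sided permutation tests between groups. With 3 samples against 3, such an exact test cannot go below p = 0.1. No 2 arrays held identical values.

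The fit and the list test were tested on simulated data with the levels of the 18193 genes. Spreads were drawn at random from the distribution that limma fitted across genes, and the simulated genes varied independently. Of 50 genes each changed by 0.5, 1, 1.5 and 2 on the log2 scale, 35, 49, 46 and 50 were recovered. Of 193 calls, 5 more were genes of the 1 shifted list and 8 were false. That list was called, and no other. Without correlation between genes, the simulation cannot tell how often camera at its preset calls lists wrongly in the real data.

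Alternatives chosen before the data were examined were other rules for the probe set of a gene, filters on dim and on less variable genes, 3 further normalizations, trended and robust variance moderation, array weights, the replicate number as a block, each sample left out in turn, an equal-variance test, other thresholds and other list tests. Chosen after seeing the data were the Y-linked signal and the spiked control signal as covariates, the omission of genes on the X and Y chromosomes, and the omission of the 2 aged samples with high pituitary transcripts, taken as a mean of Pomc and Prl more than 1 above the highest young sample. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.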

Results

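Transcript levels were measured on 6 arrays, 3 of auditory nerve from young adult mice and 3 of auditory nerve from aged mice. The auditory nerve carries the axons of the spiral ganglion neurons from the cochlea to the brainstem. Its outer part is myelinated by Schwann cells and its part nearest the brain by oligodendrocytes. The design asks which transcripts differ between the ages. A total of 18193 genes were compared.

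The aged samples had lower levels of oligodendrocyte, cholesterol synthesis, collagen and bone matrix transcripts by camera at its preset correlation. None of these 4 lists kept that call with an estimated correlation (adjusted p = 0.609, 0.528, 0.528 and 0.55). Mog, a surface protein of central myelin, was 2.87-fold lower, and Col11a2, a chain of a cartilage collagen, was 1.82-fold lower. Higher in aged nerve were Jchain, the joining chain of secreted IgA and IgM (3.20-fold), Lpl, a lipase that releases fatty acids from lipoproteins (2.90-fold), and the B cell attractant Cxcl13 (2.24-fold). In all, 116 genes passed the threshold, 26 higher and 90 lower in aged. Of these, 13 changed at least 2-fold, 6 upward and 7 downward.

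Among the 116 genes the absolute log2 change ran from 0.31 to 1.95, with a median of 0.56. All 116 had aged values on 1 side of the young values. So did 4072 of all genes (22.4%), where chance orderings of 3 against 3 give 10%. The median log2 change over all genes was −0.0085. At an unadjusted p below 0.05 there were 2917 genes.

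The count of calls depended on every sample. With aged sample 1 or young sample 1 left out, limma called 0 genes (2115 and 2243 at an unadjusted p below 0.05), without aged sample 2 it called 2, without young sample 3 it called 5, and without young sample 2 or aged sample 3 it called 23. All 116 genes kept their direction in each case, which was fixed in advance, since their groups did not overlap. A fit with the Y-linked signal as a covariate called 4 genes, one with the spiked control signal called 0 (1755 at an unadjusted p below 0.05), and one without the 2 aged samples with high pituitary transcripts called 0 (1314), where the lone aged sample is assumed to vary like the young.

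Among the genes past the threshold, Jchain (probe set 1424305_at) rose most, going from 5.31 ± 0.46 in young to 6.99 ± 0.18 in aged samples (log2 level, SD, n = 3; log2 change 1.68, SE 0.22, adjusted p = 0.0407). Ceacam10, a member of the carcinoembryonic antigen family (probe set 1417074_at), rose by 1.60 (SE 0.18, adjusted p = 0.0317), although the lowest of its 3 probe sets gave 0.27. Lpl (probe set 1415904_at) rose by 1.54 (SE 0.13, adjusted p = 0.0226), with 1.52 on its other probe set. Cbln1, a secreted organizer of synapses, rose by 1.22 and Cxcl13 by 1.16, the other Cxcl13 probe set giving 0.35. Trpa1, an ion channel that senses irritants, rose by 1.10. The protocadherin Pcdhb9 (0.79), the chromatin protein Hmgb2 (0.72), the alcohol dehydrogenase Adh1 (0.71) and the magnesium transporter family member Nipal1 (0.69) completed the 10 largest rises past the threshold, clone-like symbols left out.

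Aplnr (probe set 1438651_a_at), the receptor for apelin, fell most of the genes past the threshold, from 8.74 ± 0.40 to 6.79 ± 0.32 (log2 level, SD, n = 3; log2 change −1.95, SE 0.23, adjusted p = 0.0321). Its second probe set gave −0.32. The angiotensin precursor Agt, made by astrocytes in the brain, fell by 1.14 and the GABA receptor subunit Gabrb2 by 1.07, with a dimmer Gabrb2 probe set at 0.031. Wif1, a secreted inhibitor of Wnt signals, fell by 0.97, and the transcription factor Hhex by 0.95. The smallest adjusted p of all genes was that of Col11a2 (probe set 1423578_at), 0.00457, with levels of 9.67 ± 0.021 in young and 8.81 ± 0.016 in aged samples (SD, n = 3). Of the named genes past the threshold, 17 had more than 1 probe set and 3 of these (Gabrb2, Phex and Cntn2) had a probe set of the opposite sign.

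**Figure D1:**
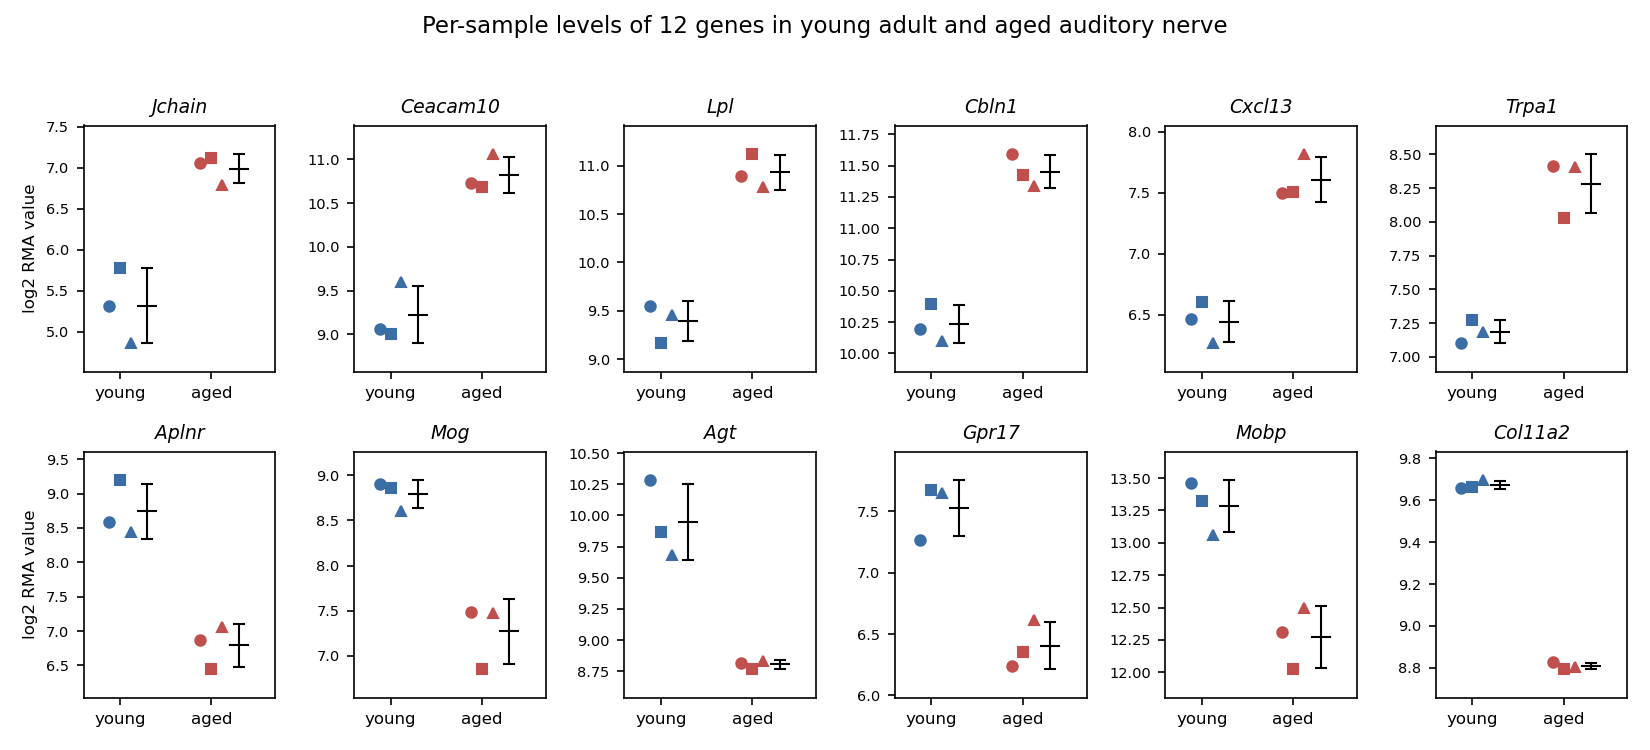
Log2 RMA value (vertical axis, not starting at 0) of 12 genes in each of the 3 young adult (blue) and 3 aged (red) samples, with circles, squares and triangles for samples 1, 2 and 3 and the black bar for the mean ± SD. In each panel the groups do not overlap, as for Col11a2, with means of 9.67 in young and 8.81 in aged.

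Oligodendrocyte and central myelin transcripts were lower in aged nerve as a group. Of 16 measured members, 5 fell and none rose past the threshold over all genes, and 12 fell when adjusted over the list alone. Mog (probe set 1448768_at) fell by 1.52 (SE 0.18, adjusted p = 0.0329), Mobp, another protein of central myelin, by 1.01 (SE 0.15, adjusted p = 0.0471, with −0.40 on its dimmest probe set), Tspan2, a membrane protein of myelinating oligodendrocytes, by 0.86 (−0.11 on the dimmest of its 3 probe sets) and the transcription factor Nkx6-2 by 0.66. Gpr17, a receptor of oligodendrocyte precursors outside the list, fell by 1.13. The list median was −0.52, and camera gave an adjusted p of 2.22e-06, against an adjusted p = 0.609 with an estimated correlation. Each aged sample lay below each young sample in the mean of the list.

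Myelin genes that both glial types use had a smaller median change. Fa2h, which makes the hydroxylated fatty acids of myelin lipids, was the 1 member of 15 that fell past the threshold (log2 change −0.52, SE 0.074, adjusted p = 0.0468), with a list median of −0.081 and 3 members lower when adjusted over the list alone. Camera gave an adjusted p of 0.0393 at the preset and an adjusted p = 0.733 with an estimated correlation, and the call was also lost without young sample 1 (0.0754), young sample 2 (0.163, median −0.048) or aged sample 1 (0.163), without the 40% dimmest genes (0.115) or the less variable 50% (0.103), with the replicate number as a block (0.0635) or the Y-linked covariate (0.131), without the 2 aged samples with high pituitary transcripts (0.271) and by camera on ranks (0.0636). Mbp, the basic protein of myelin, gave 0.024 (SE 0.047, adjusted p = 0.844) on its brightest probe set and −0.35 on the one farthest off. The brightest (14.56 in young and 14.59 in aged samples) lay near the highest array value of 14.95, where changes may be compressed. The RNA-binding protein Qk gave 0.12 (SE 0.069, adjusted p = 0.457) on its brightest and up to 0.55 on its other probe sets. Among 13 peripheral myelin and Schwann cell genes limma called 0 (4 at an unadjusted p below 0.05, and 1 higher and 1 lower when adjusted over the list alone). These 2 were Egr2, the transcription factor of myelinating Schwann cells, at 0.67 (SE 0.16, adjusted p = 0.125 over all genes) and the neurotrophin receptor Ngfr at −0.23 (SE 0.060, adjusted p = 0.144, with 0.084 on its dimmest probe set). The list had an adjusted camera p of 0.855, with a median of −0.040, a mean of 0.018 and the direction down.

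Astrocyte and satellite glia markers were also lower by camera (median −0.13, adjusted p = 0.00848, and adjusted p = 0.616 with an estimated correlation). Limma called 0 of 13 members (6 at an unadjusted p below 0.05), and 6 fell when adjusted over the list alone. Gfap, the intermediate filament of astrocytes, gave −0.58 (SE 0.13, adjusted p = 0.108) and the water channel Aqp4 gave −0.43 (SE 0.090, adjusted p = 0.0941). The list no longer passed without young sample 2 (adjusted p = 0.0739), and its median was −0.22 without aged sample 1.

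Cholesterol synthesis genes were lower throughout: all 19 measured members had a negative change, with a median of −0.22. Cyp51, which demethylates lanosterol, fell by 0.52 (SE 0.070, adjusted p = 0.042), and Srebf2, the transcription factor that switches on the pathway, fell by 0.49 (SE 0.069, adjusted p = 0.0468), although its second probe set gave −0.098. They were the 2 members past the threshold over all genes, and 11 fell when adjusted over the list alone. The camera adjusted p was 2.39e-08, and adjusted p = 0.528 with an estimated correlation.

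Fibrillar collagens and their processing enzymes were lower in aged samples, with 3 of 23 members past the threshold, 11 lower when adjusted over the list alone and a median of −0.32. Col5a2 fell by 0.93 (SE 0.10, adjusted p = 0.0317), Col11a2 by 0.86 (SE 0.043) and Col1a2, a chain of the main collagen of bone and connective tissue, by 0.60 (SE 0.075, adjusted p = 0.0373). The camera adjusted p was 4.21e-08, and adjusted p = 0.528 with an estimated correlation, and the median was −0.189 without young sample 1 and −0.172 without aged sample 2. Markers of bone moved with the collagens: all 11 osteoblast and bone matrix genes had a negative change, with a median of −0.74. Phex, an enzyme of bone-forming cells, fell by 0.97 (SE 0.10, adjusted p = 0.0284), with a dim second probe set at 0.096, and Dlx5, a transcription factor of the osteoblast lineage, gave −0.74 (SE 0.11, adjusted p = 0.0501). Adjusted over the list alone, 9 bone genes were lower. Camera gave an adjusted p of 8.73e-08, and adjusted p = 0.55 with an estimated correlation. The samples were dissected cochlear tissue, and which tissue in them gave the bone transcripts was not tested.

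Antigen presentation genes were higher by camera (median 0.29, adjusted p = 0.00394), a call that ended with an estimated correlation (adjusted p = 0.768). Limma called 0 of 16 members over all genes (4 at an unadjusted p below 0.05) and 4 higher when adjusted over the list alone. The class II chains H2-Aa at 1.48 (SE 0.27, adjusted p = 0.0726, with 0.27 on its dimmest probe set) and H2-Ab1 at 1.12 (SE 0.21, adjusted p = 0.0745) had the smallest p. The call was also lost without young sample 1 (median 0.159, adjusted p = 0.054) or young sample 2 (median 0.134, adjusted p = 0.106), and the median was 0.63 without young sample 3. Chemokine and cytokine genes were higher with 2 of 19 members past the threshold, Cxcl13 and Cxcl12, a chemokine of stromal cells (log2 change 0.49, SE 0.056, adjusted p = 0.0319, with 0.018 on the lowest of its 3 probe sets). Adjusted over the list alone, 4 were higher, the median was 0.085, and camera gave an adjusted p of 0.0158, and adjusted p = 0.616 with an estimated correlation. This call was lost without young sample 2 (0.0739) or aged sample 3 (0.199, with a median of 0.0039), with the probe set of largest interquartile range (0.0559), without the 40% dimmest genes (0.151), with array weights (0.062) and by camera on ranks (0.0787). The median was 0.0459 without young sample 1, 0.0466 without aged sample 1 and 0.138 without aged sample 2.

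Stria vascularis and melanocyte genes were higher by camera (median 0.28, adjusted p = 0.000173, and adjusted p = 0.416 with an estimated correlation). The stria vascularis is the pigmented epithelium of the cochlear side wall. Limma called 0 of 13 members over all genes (8 at an unadjusted p below 0.05), and 5 rose when adjusted over the list alone. Dct, an enzyme of melanin synthesis, gave 1.53 (SE 0.30, adjusted p = 0.0791) and the tyrosinase gene Tyr gave 0.49 (SE 0.12, adjusted p = 0.126, with 0.11 on the lowest of its 3 probe sets). Without the 40% dimmest genes the list no longer passed (adjusted p = 0.163). This list had the smallest adjusted p by fry, 0.0293. By that test 4 lists passed, the other three being cholesterol synthesis, fibrillar collagens, and spiral ligament fibrocyte and otic capsule genes, each with an adjusted p of 0.0483. The other 6 lists past the camera threshold did not pass by fry: oligodendrocyte (adjusted p = 0.0549), bone matrix (0.0549), astrocyte (0.131), shared myelin (0.186), chemokine (0.23) and antigen presentation (0.527).

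**Figure D2:**
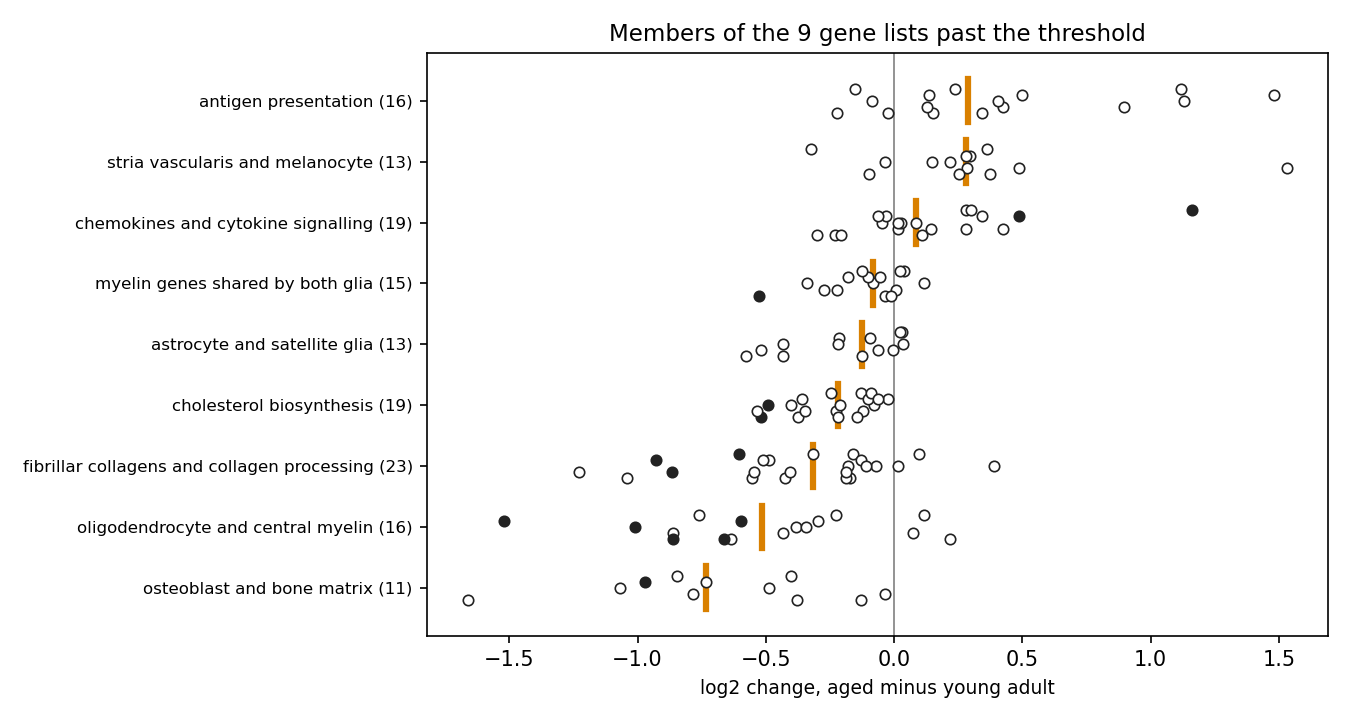
Log2 change, aged minus young adult (horizontal axis), of each measured member of the 9 gene lists past the camera threshold, with the number of members in brackets, filled circles for genes past the threshold over all genes, open circles for the others and an orange bar for the list median. Medians run from −0.74 for bone matrix to 0.29 for antigen presentation, and the vertical spread within a list has no meaning.

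Neuronal lists did not pass, although 3 of the 5 did in other settings of the fit. The spiral ganglion neuron identity list had a median of −0.055 (adjusted p = 0.428 by camera). Limma called 0 of its 17 members, with 0 at an unadjusted p below 0.05. It also called 0 of 18 neurofilament, 16 presynaptic and 14 ion channel genes, with 6, 2 and 4 at an unadjusted p below 0.05 and 2, 0 and 4 lower when adjusted over the list alone. Neurofilament and axonal cytoskeleton genes had a median of −0.048 (adjusted p = 0.0542), with the neurofilament chain Nefm at −0.36 (SE 0.071, adjusted p = 0.0811), Nefl at −0.069 (SE 0.041, adjusted p = 0.46) and the neuronal tubulin Tubb3 at −0.28 (SE 0.093, adjusted p = 0.218). Presynaptic genes (median −0.018, adjusted p = 0.547) and neuronal ion channel and glutamate receptor genes (median −0.047, adjusted p = 0.0836) did not pass, the potassium channel Kcnq3 giving −0.35 (SE 0.074, adjusted p = 0.0947, with −0.14 on its dimmer probe set). Of 16 node and paranode genes (adjusted p = 0.394), Cntn2, an adhesion protein of the region beside the node of Ranvier, fell by 0.49 (SE 0.049, adjusted p = 0.0284), with a dimmer probe set at 0.024. By camera the neurofilament, ion channel and node lists were lower with the Y-linked covariate (adjusted p = 0.0379, 0.00397 and 0.0187). Without the 2 aged samples with high pituitary transcripts their medians were −0.068, −0.132 and −0.064. Both fits were chosen after seeing the data. They set mainly aged sample 3 against the young samples, since the aged samples with high pituitary transcripts also had the low Y-linked signal. The ion channel list was also lower without aged sample 2 (0.0122, median −0.077), and the neurofilament list without aged sample 2 (0.00842) or young sample 3 (0.0269), without the less variable 50% of genes (0.0121), with quantile normalization (0.0492) and with the spiked control covariate (0.0114).

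Immune cell lists other than antigen presentation and chemokines did not pass. Macrophage and microglia genes had a median of −0.022 (adjusted p = 0.811), but were higher by camera with the Y-linked signal as a covariate (macrophage and microglia median 0.14, adjusted p = 0.0304). Without the 2 aged samples with high pituitary transcripts their median was 0.17. Both fits were chosen after seeing the data and set mainly aged sample 3 against the young samples. With all 6 samples and no covariate, Laptm5 had the smallest p of the list, at −0.38 (SE 0.060, adjusted p = 0.0537, with 0.12 on the probe set farthest off). It was the 1 member lower when adjusted over the list alone. In the same fit the lysosomal marker Cd68 was at 0.35 (SE 0.10, adjusted p = 0.188), the microglial receptor Cx3cr1 at −0.36 (SE 0.16, adjusted p = 0.324, with −0.0081 on its dimmer probe set) and the complement chain C1qa at 0.024 (SE 0.13, adjusted p = 0.95). The complement list had an adjusted p of 0.719 (median −0.0064, mean 0.029, direction up), and the interferon response list one of 0.719 (median 0.050, mean −0.016, direction up). Of 11 B cell and plasma cell genes (adjusted p = 0.267), Jchain rose past the threshold. T cell and NK cell genes (adjusted p = 0.0547) and neutrophil genes (adjusted p = 0.0536) did not pass, but the first were higher without young sample 3 (0.028) or aged sample 2 (0.00842) and the second lower without young sample 2 (0.0312), young sample 3 (0.000597) or aged sample 3 (0.004). The neutrophil list had a median of −0.57 and differed between samples of a group, the young samples lying at 0.933, −0.271 and −0.662 around their mean. Erythroid genes gave an adjusted p of 0.43.

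Among the structural and vascular lists, basement membrane (adjusted p = 0.0542), pericyte and smooth muscle (0.153), spiral ligament fibrocyte and otic capsule (0.235), endothelial (0.394), fibroblast (0.855) and skeletal muscle genes (0.811) did not pass by camera. Basement membrane genes were lower without young sample 2 (0.0312), aged sample 1 (0.0142) or aged sample 2 (0.0189), and pericyte and smooth muscle genes without young sample 2 (0.0312). Limma called 0 genes in these lists, with 6, 3, 4, 4, 1 and 1 members at an unadjusted p below 0.05. Adjusted over the list alone, 3, 3, 4, 2, 0 and 0 were lower, and 1 skeletal muscle gene was higher. The endothelial tight junction gene Cldn5 gave −0.55 (SE 0.14, adjusted p = 0.139), and Pou3f4, a transcription factor of the otic mesenchyme, gave −0.58 (SE 0.094, adjusted p = 0.0563). Hair cell genes (adjusted p = 0.351) and supporting cell and tectorial membrane genes (0.745, median −0.010, mean 0.035, direction up) did not pass either, the first being lower without young sample 3 (adjusted p = 0.00925). The skeletal muscle list had a median of −0.087, a mean of −0.028 and the direction up.

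Lists for cell states did not pass: mitochondrial respiratory chain (adjusted p = 0.144), circadian clock (0.0836), p53 and senescence (0.634), immediate early (0.745), oxidative stress defence (0.917), heat shock and chaperone (0.917), cell cycle (0.917) and lysosome and lipid handling genes (0.917). Without young sample 3 the circadian clock list was higher and the immediate early list lower (adjusted p = 0.0269 for each), and the clock list was also higher without aged sample 3 (0.0431). The senescence gene Cdkn2a differed by 0.011 (SE 0.12, adjusted p = 0.977), at levels near background (4.83 ± 0.14 in young and 4.84 ± 0.23 in aged samples, SD, n = 3). Hmgb2 of the cell cycle list and Lpl of the lysosome and lipid list were the members past the threshold, both higher. Adjusted over the list alone, 3 immediate early genes were higher and 4 lower, and 1 lysosome and lipid gene was higher and 3 lower. The clock, senescence and cell cycle lists each had 1 higher and 1 lower. The median, mean and direction of the oxidative stress list were −0.012, 0.014 and down, and those of the lysosome list 0.00077, 0.059 and down. In all, 9 of the 38 lists tested passed by camera at the preset correlation, 3 higher and 6 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.416. Of the 29 lists that did not pass, 16 passed in at least 1 other setting of the fit: the neutrophil list in 11, the basement membrane and neurofilament lists in 7 each, the T cell and circadian clock lists in 5 each and the others in 1 to 4, among them interferon response without young sample 3 (interferon response median 0.51, adjusted p = 2.14e-08). The cell cycle list was higher without the 40% dimmest genes (cell cycle median 0.084, adjusted p = 0.0365) and with the spiked control covariate (0.062, adjusted p = 0.0465) against a median of −0.031 with all genes and no covariate. Other splits of the same 6 samples into 3 and 3 gave up to 13 lists past the threshold.

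Some signals differed between samples of one group. The mean log2 level of 3 Y-linked genes was 8.95, 8.86 and 9.81 in young samples 1 to 3, and 4.50, 5.39 and 9.85 in aged samples 1 to 3. Xist, the transcript of the inactive X chromosome of females, was at 12.76, 12.86 and 7.09 in the young and 13.51, 13.51 and 9.08 in the aged samples. Young samples 1 and 2 thus carried both signals, young sample 3 and aged sample 3 mainly the Y-linked one, and aged samples 1 and 2 mainly Xist. All young samples but only aged sample 3 of the aged group had a high Y-linked signal, so the groups were not matched in sex makeup. The 4 measured genes of the sex-linked list, too few for the list test, had a median change of −2.48, and limma called 0 of them (0 at an unadjusted p below 0.05), the Y-linked Kdm5d giving −2.54 (SE 1.25, adjusted p = 0.379, with −0.055 on the probe set farthest off).

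Pituitary hormone transcripts were high in aged samples, with Pomc and Prl highest in samples 1 and 2. Pomc, the precursor of corticotropin, was at 7.86, 8.68 and 7.83 in the young samples and at 10.36, 14.19 and 8.42 in the aged samples 1 to 3. The prolactin transcript Prl was at 5.76, 6.74 and 6.26 against 9.88, 12.26 and 7.10, and the growth hormone transcript Gh at 6.96, 7.73 and 7.66 against 8.77, 9.84 and 9.11. Aged sample 3 thus lay above each young sample in Prl and Gh, and above aged sample 1 in Gh. The exact two-sided permutation p was 0.2 for Pomc, and 0.1, the smallest the design allows, for Prl and for Gh (n = 3 per group).

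RNA quality controls lay close together in both groups. The log2 difference between the 3' and 5' probe sets was 0.14 ± 0.036 in young and 0.14 ± 0.031 in aged samples for Gapdh (SD, n = 3; exact permutation p = 0.9), and 0.82 ± 0.044 and 0.80 ± 0.057 for beta-actin (exact permutation p = 0.5). Pearson correlations over all genes were 0.996 in each pair of young samples, and ran from 0.996 to 0.998 between aged samples and from 0.994 to 0.997 between groups. The first principal component held 41.8% of the variance, with young samples at −15.8, −5.66 and −14.1 and aged samples at 15.9, 17.0 and 2.71.

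**Figure D3:**
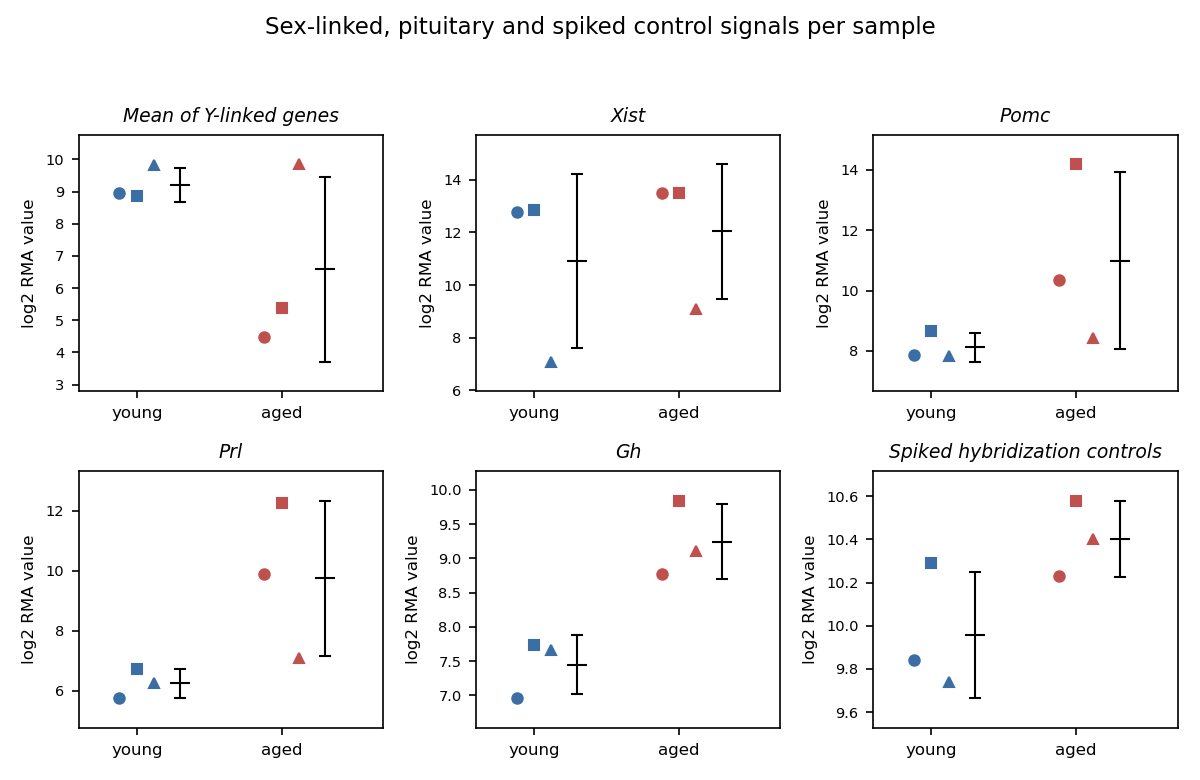
Log2 RMA value (vertical axes, not starting at 0) per sample of the mean of 3 Y-linked genes, of Xist, of the pituitary transcripts Pomc, Prl and Gh, and of the mean of the spiked hybridization controls, in young adult (blue) and aged (red) samples, with circles, squares and triangles for samples 1, 2 and 3 and the black bar for the mean ± SD (n = 3). Pomc reaches 14.19 in aged sample 2 and 10.36 in aged sample 1, above the young samples at 7.83 to 8.68.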

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

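The tests of prolactin in females, of carry-over in aged sample 1 and of the oligodendrocyte genes were chosen only after the results were seen, and so was the fit with the Y-linked signal as a covariate.

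Control transcripts added to the samples, outside the comparison of genes, read brighter on the aged arrays. The spiked hybridization controls differed by 0.447 on the log2 scale (aged minus young; 9.96 ± 0.29 against 10.40 ± 0.18, SD, n = 3, exact two-sided permutation p = 0.2). The spiked poly-A controls differed by 0.465 (7.80 ± 0.24 against 8.27 ± 0.17, SD, n = 3, exact two-sided permutation p = 0.1, the smallest the design allows). Among probe sets with several gene names or unnamed here, which entered no comparison of the report, 30 passed the threshold (14 higher and 16 lower in aged) when all probe sets were tested together, out of 172 past it.

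Pituitary hormone transcripts in aged samples 1 and 2 were weighed against carry-over of pituitary tissue, the gland lying near the skull base, and against the higher prolactin of females. In aged sample 2 the median excess of 13 other pituitary genes over the young mean was 0.256, above the 95% range of 10000 random gene sets matched on level (−0.082 to 0.076), with the gonadotropin chain Cga 3.39 above (1.13 in aged sample 1 and 0.928 in aged sample 3), which is consistent with carry-over in that sample. In aged sample 1 it was 0.0206, inside the range of its random sets (−0.086 to 0.073), which leaves carry-over there open, since only 2 of the 13 had a young mean above the array median. In aged sample 3, where Prl and Gh also lay above each young sample, it was 0.0301, inside its range too (−0.072 to 0.082), so carry-over there stays open as well. Higher prolactin of females at both ages is argued against by young samples 1 and 2, which carried Xist too but whose Prl lay at least 3.14 below that of aged samples 1 and 2, more than the log2 step of 1 for a 50% share of female RNA and the young range of 0.98 together. Higher prolactin of aged females only, and a change of the aged nerve itself, stay open and untested, and none of the 13 genes is in a fixed list.

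The sex makeup of the samples, read from Xist and Y-linked genes, was weighed for the 9 gene lists past the threshold. All 9 kept at least 50% of their mean shift and their direction with the Y-linked signal as a covariate, although the shared myelin list lost its call (mean shift −0.12 before and −0.074 after, camera adjusted p = 0.131). That signal was at 9.85 in aged sample 3 but at 4.50 and 5.39 in aged samples 1 and 2, which also had high pituitary transcripts. The fit thus sets mainly aged sample 3 against the young samples, and cannot decide how far sex makeup moved these lists. For single genes the same covariate left 1 of the 116 calls (Col11a2) and all 116 directions, and it takes up 1 of few residual degrees of freedom, so how far sex adds to single genes stays open. Of the 10 splits of the 6 samples into 3 and 3, the real one included, 1 gave at least 116 genes, the real one itself (0 for the highest other), and 5 gave at least 9 lists, the real one among them (13 for the highest other). For genes, these splits are too few for a share under 0.05. For lists, 5 of the 10 splits reached the real count, so the number of lists called does not set the age groups apart.

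Lower oligodendrocyte genes in aged were weighed against less central nerve tissue in the aged samples, dilution by other tissue, and sex makeup. The oligodendrocyte-only set, 13 genes of which 11 are also in the fixed list, had a median of −0.66. Chosen after the results were seen, it left out all list members with a positive change (Aspa 0.218, Bcas1 0.0753 and Tmem125 0.115), besides Cldn11 and Myrf. It added Gpr17 (−1.13) and Nkx2-2 (−0.33), so its median and signs were partly set by that choice. Dilution is argued against by the neuronal identity list, whose median was −0.0548, with 1 of 17 members below 50% of that fall. With the Y-linked signal as a covariate the set kept a median of −0.625, all 13 members staying negative. That fit sets mainly aged sample 3 against the young samples, so it cannot decide how far sex makeup lowered the set. Less central tissue, such as a nerve severed closer to the cochlea, stays open. It would lower central astrocyte genes too, and 16 of them, 4 in the fixed astrocyte list, had a median of −0.433. If the amount of central tissue also varied within groups, both sets would move together there, which was not shown. Over the deviations of the 6 samples from their group means Pearson's r was 0.754 and Spearman's rho 0.657 (exact two-sided permutation p within groups = 0.194 and 0.25). Without the 2 samples farthest out in the oligodendrocyte set r was −0.212, but leaving them out also removes much of the spread that r rests on. A loss of central glia with age would also lower both sets and stays open and untested.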

How the results depend on the processing

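The Y-linked and spiked control covariates, the omission of X and Y genes and that of the 2 pituitary-rich aged samples were chosen after seeing the data. Of the 116 genes, those tested in a setting with 1 value per gene kept their direction in it (91 without the 40% dimmest genes, 112 without X and Y genes, 116 in the others). Where samples were left out or weighted, that direction could not change, since the groups of these genes did not overlap. It was also fixed under the gene filters, the omission of X and Y genes and the replicate block, which keep the same group means. The same holds for the variance moderation, the equal-variance test and the other thresholds. Only the other probe set rules, the further normalizations and the covariates could have changed it. The 9 lists kept their direction too, but the count of calls moved widely. The cause was not tested except where fewer samples, genes or a stricter threshold set it. Calls past the threshold, then higher and lower, were 218, 61 and 157 with the probe set of largest interquartile range, 226, 49 and 177 without the 40% dimmest genes, 192, 55 and 137 without the less variable 50%, 252, 63 and 189 with trend and robust moderation, and 354, 89 and 265 with array weights. They were 4, 3 and 1 with the Y-linked covariate, 0, 0 and 0 with the spiked control covariate (limma, 1755 at unadjusted p below 0.05) and without the pituitary-rich samples (1314), and 2, 0 and 2 by the equal-variance test. Thresholds gave 482, 136 and 346 (adjusted p below 0.10), 51, 13 and 38 (with 1.5-fold), 13, 6 and 7 (with 2-fold) and 188 and 66 higher (unadjusted p below 0.05 with 1.5-fold). Tested per probe set, 40 genes were higher. Leaving out 1 sample gave 0 to 23 calls, 0 to 7 higher and 0 to 16 lower. Quantile, median and loess normalization gave 102, 121 and 110 calls.

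Same-numbered samples did not deviate together (correlations 0.0072, 0.059 and −0.024), which gave no sign of a pairing but cannot exclude that they were processed together. With the number as a replicate block limma called 0 genes, 0 higher and 0 lower (2802 at unadjusted p below 0.05), and 8 of the 9 lists passed. Lists higher and lower were 5 and 10 with the Y-linked covariate, 8 higher with the spiked control covariate, 7 and 10 without the pituitary-rich samples, 0 and 0 with an estimated correlation, 1 and 3 by fry, and from 1 to 6 higher and 5 to 10 lower with 1 sample left out. The macrophage and microglia list turned up with the Y-linked covariate (median 0.14, adjusted p = 0.0304) and without the pituitary-rich samples (median 0.17), fits that both set mainly aged sample 3 against the young samples. The cell cycle list turned up without the 40% dimmest genes (0.084, adjusted p = 0.0365) and with the spiked control covariate (0.062, adjusted p = 0.0465). Named genes past the threshold kept their call in 378 of their other values and lost it in 338, and those short of it passed in 72; called lists kept theirs in 173 and lost it in 34. The first component held 46.4% over the 1000 most variable genes.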

Other observations

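The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were higher in each aged sample than in each young one, with a median log2 change of 1.12. H2-Eb1 gave 1.13 (SE 0.28, adjusted p = 0.131 by limma) and Cd74, the chain that guides class II molecules to the lysosome, gave 0.90 (SE 0.21, adjusted p = 0.115). None of the 4 passed over all genes, although each was below 0.05 before adjustment. Of 22 measured genes of the protocadherin beta cluster, neuronal adhesion proteins encoded side by side, Pcdhb9 (0.79) and Pcdhb3 (0.48, SE 0.067, adjusted p = 0.046) rose past the threshold while the cluster's median was 0.031, with 11 genes positive. The theta class glutathione transferases Gstt1 (0.36), Gstt2 (0.26) and Gstt3 (0.34) each missed the threshold over all genes (adjusted p = 0.103, 0.0701 and 0.0662), and Gstt4 gave 0.028. These families, H2-Eb1, Cd74, Pcdhb3 and the Gstt genes were chosen after their values were seen.

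Bone markers outside the naming rule, picked after their values were seen, did not pass over all genes. Ibsp, a phosphoprotein of mineralized bone, gave −1.66 (SE 0.26, adjusted p = 0.0527), Mepe, a protein of osteocytes, gave −1.07 (SE 0.28, adjusted p = 0.144) and Sost, the osteocyte inhibitor of Wnt signals, gave −0.85 (SE 0.17, adjusted p = 0.0854, with −0.043 on its dimmer probe set). The mean of the bone list relative to the young mean was 0.232, −0.216 and −0.016 in young samples 1 to 3 and −0.627, −0.833 and −0.586 in aged samples 1 to 3. For the fibrillar collagens it was 0.087, −0.095 and 0.0078 against −0.292, −0.501 and −0.328. Interferon response genes stood high in young sample 3, at 0.967, with the other young samples at −0.572 and −0.395 and the aged samples at −0.112, 0.335 and −0.270.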
